A study of Rattus norvegicus with 6 samples.

How the data were processed

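The data were RNA-seq profiles of rat aorta from 6 libraries, 3 from rats given engineered exosomes and 3 from rats given saline, grouped by the treatment named in the labels. Per the labels' protocols, total RNA was made into libraries with the SMARTER mRNA-seq kit. The authors deposited gene expression as FPKM, in a single table of 24005 gene symbols and 6 columns, each of which matched the title of 1 sample. DESeq2 1.28.1 is listed in the submitters' processing notes, with no role given. The aligner, the counting tool, the strand setting, the genome build and the annotation are not given in the sources used here, so no coordinates are printed. Reads of overlapping genes, antisense genes, paralogs and pseudogenes could not be separated further. The labels speak of rats in each group but do not say that each library came from a different animal, so p-values measure the spread between these samples.

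FPKM values of a gene were whole multiples of 1 step per library. From these steps whole reads were recovered for 18430 genes, 100.0% of those above 0 in any library, within 0.02 reads, and the implied library totals ranged from 28063355 to 44561082. Whether 1 unit was a read or a read pair could not be told. Gene lengths came from the same steps. Recovered reads on genes made up 98.6% to 98.9% of the implied totals. No pair of libraries was a duplicate: the chi-square of recovered reads ranged from 48.6 to 193.5 per gene. Counting error is therefore small for genes with many reads and large for the short microRNA features. Listed symbols were matched to the table directly or through synonyms of the GRCr8 gene table, which served for names only. Of the symbols in the deposited table, 17871 matched a current symbol and 2138 only a synonym.

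The test was limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with empirical Bayes moderation and an intensity trend, two-sided, for the 11742 genes with a mean FPKM of at least 1 over the 6 libraries. P-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. No covariate was used. Log2 differences are on the log2(FPKM + 1) scale, which understates the change of low genes. FPKM is relative to the library total, and the median log2 difference of all genes was -0.073, with 39.3% of genes higher. After rescaling to the median of ratios it was -0.006, with 49.0% higher. SDs are of the FPKM values within a group, and standard errors are limma's.

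Gene lists were tested with camera in limma on the same values, with a preset inter-gene correlation of 0.01 and adjustment over the 33 of 35 lists with at least 5 tested members. Camera compares a list with all other genes, so a list that rose or fell did so relative to them. Counts of members adjusted over the list alone used the same p-values. Lists, list members, tests and all but the alternatives named as added were chosen before the data were examined. Genes were named by a rule chosen then too. It took all genes past the threshold whose groups did not overlap, filled to 10 higher and 10 lower by the smallest unadjusted p among genes with an assigned symbol. It added 16 genes of smooth muscle, calcification and the series title, and up to 4 members with the smallest p of each list described in detail. Some members that the rule takes are not reported here. Genes named outside the rule were chosen after their values were seen.

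Alternatives were pseudocounts of 0.1 and 0.01, no filter and a mean FPKM of at least 5, rescaling of each library to the same sum (TPM), rescaling to the median of ratios, quantile normalization, moderation without trend and with robust moderation, library weights, a replicate block, each library left out in turn, other thresholds, camera with an estimated correlation, camera on ranks, and fry. A fit with limma-voom on the recovered reads, and a fit with exosome 1 and 3 both left out, were added after the data were seen. The fit was tested on simulated libraries of the exosome and saline comparison with 11742 genes. Of 100 genes changed 2-fold 77% were recovered, and of 100 changed 4-fold 96%, with 10 unchanged genes called, none with the wrong sign and 0 of 200 unchanged lists called. Genes varied independently in the simulation, and its libraries had no structure beside the group. It therefore cannot show how often lists of correlated genes are called by error, or the share of changes recovered in the real libraries. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used for the read recovery and the plots.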

Results

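RNA from the aorta of rats with chronic kidney disease was sequenced after treatment with engineered exosomes or with saline. Kidney disease had been induced by removal of 5/6 of the kidney mass in 2 operations, and a diet with 1.2% phosphorus was fed to speed up calcification of the vessel wall. The treated group received 10 mg/kg of exosomes, named ANCR/E7-EXO in the labels, into the tail vein at intervals of 5 days, and the control group received saline for 13 weeks. Exosomes are small vesicles released by cells. ANCR, also written DANCR, is a long non-coding RNA. Each group held 3 libraries. The values were FPKM (reads scaled to gene length and to the total of the library) for 24005 gene symbols, of which 18430 were above 0 in at least 1 library. The FPKM steps implied library totals of 33563752, 29665532 and 34009970 reads or read pairs for saline 1, 2 and 3, and of 34369879, 28063355 and 44561082 for exosome 1, 2 and 3. Mitochondrially encoded genes took 4.50%, 6.77% and 4.90% of the assigned reads in the saline libraries and 4.66%, 3.91% and 4.82% in the exosome libraries.

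The comparison asked which genes of the calcifying aorta differed between exosome-treated and saline-treated rats. Zbtb16, which encodes a zinc finger transcription factor also known as PLZF, rose with exosomes. It stood at 10.8 ± 1.76 FPKM in the saline group and 48.5 ± 3.58 FPKM in the exosome group (mean ± SD, n = 3 each), a ratio of the means of 4.50. On the log2(FPKM + 1) scale the difference was 2.08 with a standard error of 0.14, and limma gave a Benjamini-Hochberg adjusted p of 0.00806 over 11742 genes. All 3 exosome libraries lay above all 3 saline libraries for this gene. No gene fell past the threshold. At an unadjusted p under 0.05, limma found 792 genes higher and 1085 lower. Chance gives 587 such genes in all on average, with a wide spread if genes are correlated. Other splits of the same 6 libraries into 3 and 3 gave 166 to 2570 such genes in all, against 1877 for the treatment. Voom on reads recovered from the FPKM steps also called 1 gene in all, Zbtb16. The groups did not overlap for 2483 genes (21.1%), where chance gives 10% with 3 libraries against 3. The Zbtb16 call was lost without saline 3 (adjusted p = 0.0865), without exosome 1 (adjusted p = 0.0503) and with exosome 1 and 3 both left out (adjusted p = 0.124). Its log2 difference stayed between 1.96 and 2.18 in the fits that left out a single library.

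Among the genes ranked next by unadjusted p, none passed the adjusted threshold, and all of those named here had groups that did not overlap. Cyp2c22, a cytochrome P450, stood at 1.61 ± 0.505 FPKM with saline and 9.52 ± 2.23 FPKM with exosomes, a log2 difference of 2.01 ± 0.21 (SE) with an adjusted p of 0.114. Cd163, a scavenger receptor of macrophages, stood at 6.45 ± 0.533 and 14.98 ± 2.13 FPKM (adjusted p = 0.143). It passed under quantile normalization (adjusted p = 0.0490) and with library weights (adjusted p = 0.0114). Enc1 (log2 difference 1.26), Uchl3 (1.39), Tsen34 (1.45) and Hipk3 (0.69) were also higher at the same adjusted p of 0.143. Nfkbia, which encodes the NF-kB inhibitor IkB-alpha, stood at 30.1 ± 8.78 and 68.8 ± 3.91 FPKM (adjusted p = 0.219). Rpl30, a ribosomal protein gene, had a log2 difference of 1.82 (adjusted p = 0.219), which is uncertain because ribosomal protein genes share reads with processed pseudogenes. Mir1956 was also among the 10, but its 63 bp feature held only 1 to 10 reads per library.

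The lower genes were led by Mir374b, whose 68 bp feature held 0 to 10 reads per library (adjusted p = 0.174), and by Nsg2, at 3.26 ± 1.12 FPKM with saline and 0.326 ± 0.189 with exosomes (adjusted p = 0.215). Ptgs2, which encodes the inducible cyclooxygenase COX-2, had the largest difference of the 20 ranked genes. It stood at 172.2 ± 110.007 FPKM in the saline libraries and 13.6 ± 1.40 FPKM in the exosome libraries, a log2 difference of -3.31 ± 0.50 (SE) with an adjusted p of 0.219. Its saline values were 57.3, 182.7 and 276.6 FPKM, so the spread lay mainly within that group. Btg1, an antiproliferative gene, stood at 134.5 ± 35.6 and 58.2 ± 7.46 FPKM, and Dusp10, a MAP kinase phosphatase, at 5.03 ± 1.12 and 1.93 ± 0.0861 FPKM. Rasl11a (log2 difference -1.08), Tcea3 (-1.02), Ccdc77 (-1.19), Dcaf4 (-0.76) and Slc25a35 (-0.81) completed the 10. All of these lower genes from Ptgs2 on had an adjusted p of 0.219. Without saline 1, Ptgs2 (adjusted p = 0.00160) and Nfkbia (adjusted p = 0.0173) passed, and without exosome 2 Mir374b passed (adjusted p = 0.0386).

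**Figure D1:**
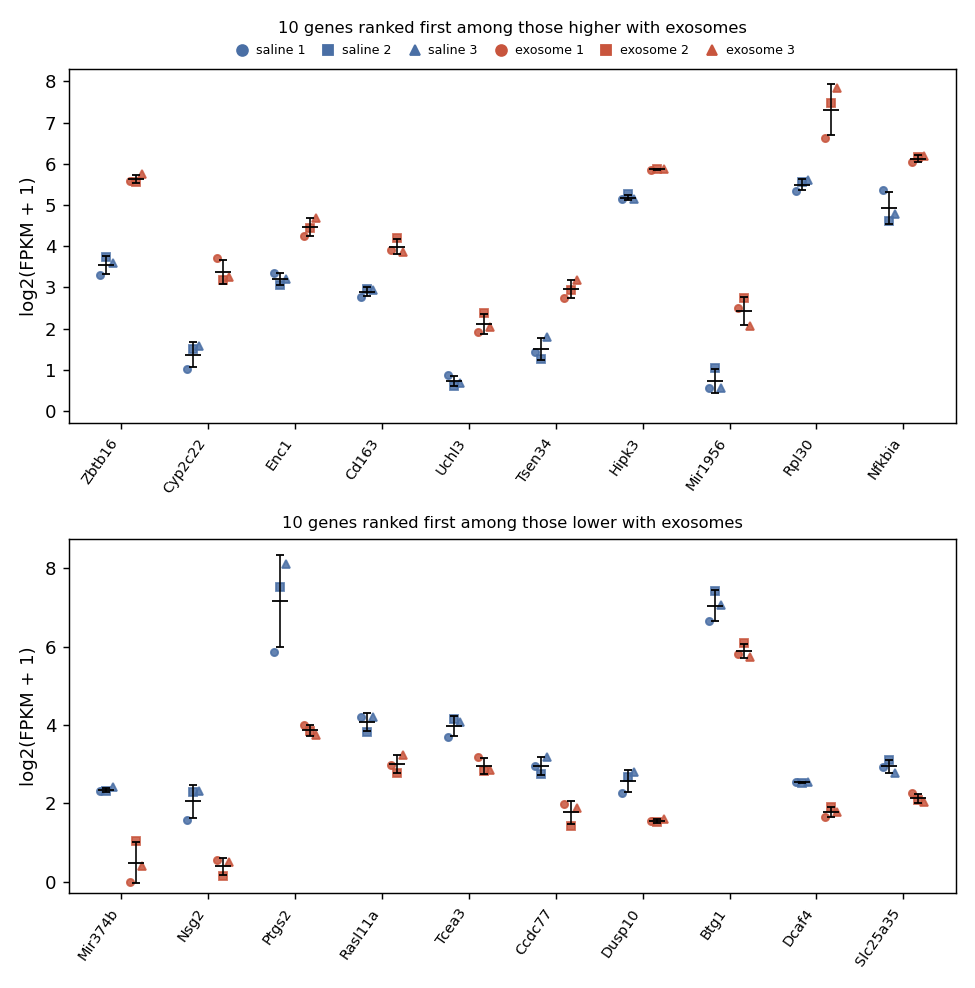
The vertical axes give log2(FPKM + 1) of the 10 genes ranked first among those higher (top) and lower (bottom) with exosomes. Symbols are single libraries, and the bars are the mean ± SD of 3 libraries per group on that scale. Zbtb16 is the only one of the 20 that passed the adjusted threshold, at 45.9 to 52.6 FPKM in the exosome libraries and 8.91 to 12.4 FPKM in the saline libraries.

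Gli1, the Hedgehog pathway transcription factor that marks the cells the series is about, stood at 3.41 ± 0.947 FPKM with saline and 3.98 ± 0.660 FPKM with exosomes, a log2 difference of 0.19 ± 0.20 (SE) with an adjusted p of 0.624. No gene under the symbol Dancr was analysed here. Of the smooth muscle genes chosen beforehand, Myocd, the coactivator that drives contractile gene expression, stood at 16.95 ± 3.84 and 33.2 ± 4.69 FPKM. Its log2 difference was 0.94 ± 0.17 (SE), and its adjusted p was 0.237 although the groups did not overlap. The contractile genes themselves differed by less than the spread between libraries. Acta2 stood at 6190 ± 2439 and 7752 ± 1839 FPKM (adjusted p = 0.579), Myh11 at 1862 ± 218.6 and 1739 ± 248.5 (adjusted p = 0.773), Tagln at 6624 ± 1194 and 6922 ± 986.9 (adjusted p = 0.892), and Cnn1 at 1158 ± 444.6 and 1441 ± 432.7 (adjusted p = 0.609).

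Genes of mineralisation did not pass either. Alpl, the tissue-nonspecific alkaline phosphatase, stood at 14.8 ± 11.1 FPKM with saline and 15.6 ± 1.51 with exosomes (adjusted p = 0.732), and saline 1 alone reached 27.3. Spp1, which encodes osteopontin, stood at 567.4 ± 192.2 and 497.6 ± 209.9 FPKM (adjusted p = 0.755). The mineralisation inhibitors Mgp, at 2485 ± 130.6 and 2424 ± 104.1 FPKM (adjusted p = 0.912), and Enpp1, at 14.8 ± 2.48 and 12.8 ± 3.03 FPKM (adjusted p = 0.581), differed by less than their spread. So did Ezh2, a histone methyltransferase (log2 difference -0.03, adjusted p = 0.915), and Klf4 (log2 difference 0.22, adjusted p = 0.569). The signs of Mgp and Ezh2 turned under rescaling to equal sums and to the median of ratios, and that of Ezh2 also under quantile normalization. Runx2, the osteogenic transcription factor, lay below the expression minimum and was outside the test. Its values were 0.900 ± 0.104 FPKM with saline and 0.507 ± 0.143 FPKM with exosomes, from 64 to 182 reads per library, and the groups did not overlap. With no filter on low values its log2 difference was -0.34 ± 0.10 (SE), with an adjusted p of 0.364 in limma. Sox9, at 0.293 ± 0.0738 and 0.437 ± 0.250 FPKM, and Bglap, which encodes osteocalcin, at 0.140 ± 0.0702 and 0.159 ± 0.143 FPKM, also lay below the minimum.

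**Figure D2:**
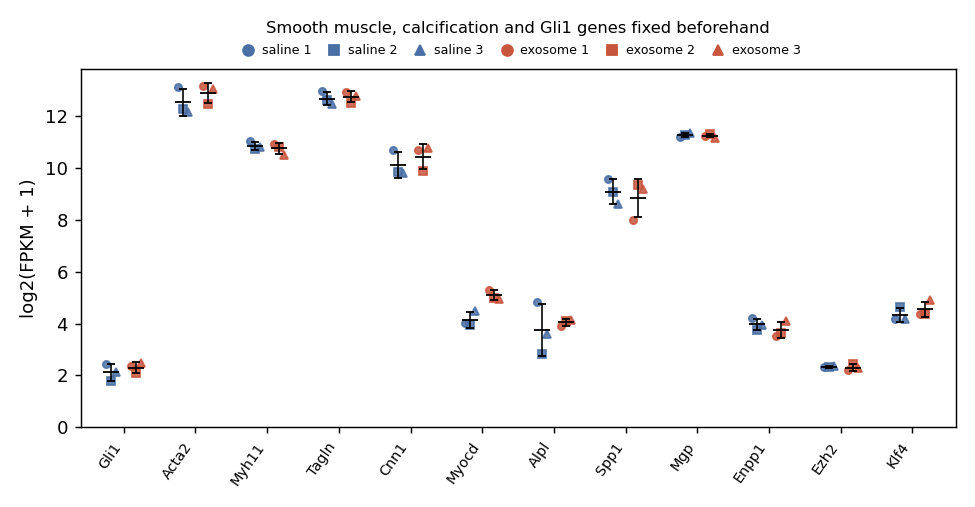
The vertical axis gives log2(FPKM + 1) of the genes chosen beforehand that could be tested. Symbols are single libraries, and the bars are the mean ± SD of 3 libraries per group on that scale. Only the groups of Myocd are apart, and none of these genes passed the adjusted threshold.

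Of the 35 gene lists chosen beforehand, 33 had at least 5 tested members, and 6 of these passed camera with its preset correlation. All 10 splits of the 6 libraries into 3 and 3, the real one included, gave at least 6 such lists. Endothelial markers rose relative to other genes, with 14 of 17 tested members higher, a median log2 difference of 0.49 and an adjusted p of 3.65e-06. The call did not hold with an estimated correlation (adjusted p = 0.925). No member passed over all genes tested, and 6 passed when adjusted over the list alone, all higher. They included Nos3, the endothelial nitric oxide synthase, at 5.89 ± 1.09 FPKM with saline and 11.4 ± 1.75 with exosomes, and the tight junction gene Cldn5, at 8.77 ± 1.57 and 17.9 ± 7.16 FPKM. Esam (log2 difference 0.49) and Ramp2 (0.59) were the next. Kdr (-0.29), Erg (-0.11) and Egfl7 (-0.07) were the lower endothelial members. Macrophage markers rose as well, with 15 of 18 tested members higher, a median of 0.27 and an adjusted p of 7.09e-06, which also did not hold with an estimated correlation (adjusted p = 0.925). None passed over all genes and 6 passed adjusted over the list alone, led by Cd163, Clec10a (11.3 ± 0.927 and 18.2 ± 1.34 FPKM), Mrc1 (10.3 ± 1.26 and 16.3 ± 0.750 FPKM) and the complement gene C1qb (15.6 ± 0.666 and 23.0 ± 3.42 FPKM). The lower members were Aif1 (log2 difference -0.30), Ms4a7 (-0.22) and Lyz2 (-0.05). The macrophage call was also lost with exosome 1 and 3 both left out (adjusted p = 0.288).

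Genes of TGF-beta and BMP signalling rose relative to other genes, with 18 of 25 tested members higher, a median of 0.17 and an adjusted p of 0.00482. With an estimated correlation the adjusted p was 0.925. None passed over all genes, and 1 passed adjusted over the list alone. This was Smad7, at 14.2 ± 3.46 and 29.2 ± 5.88 FPKM, which encodes an inhibitor of TGF-beta signalling. The ligand gene Bmp6 (log2 difference 0.66), the BMP target Id1 (0.77) and Inhba (-0.42) followed. The list's adjusted p was 0.0862 without exosome 3. It was 0.0573 with library weights and 0.288 with exosome 1 and 3 both left out.

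Heat shock genes rose relative to other genes, with all 13 tested members higher, a median of 1.06 and an adjusted p of 3.13e-04. It was lost with an estimated correlation, at an adjusted p of 0.925. No member passed over all genes or adjusted over the list alone. Exosome 1 and 3 carried the difference. The list score, the mean deviation of its members from their mean over the 6 libraries in log2 units, was 0.92 in exosome 1 and 1.62 in exosome 3. It was -1.01 in exosome 2, below the saline values of -0.86, -0.66 and -0.02. The chaperone genes with the smallest p were Chordc1 (log2 difference 1.06), Hsp90ab1 (0.93), Hsp90aa1 (1.32) and Hsph1 (1.77). Hsph1 stood at 52.5 ± 26.9 FPKM with saline and 257.4 ± 237.7 FPKM with exosomes. With exosome 1 and 3 both left out the list turned to lower, at an adjusted p of 0.0171, with exosome 2 as the lone treated library, which was assumed to vary like the saline libraries.

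Interferon response genes fell relative to other genes, with 19 of 23 tested members lower, a median of -0.39 and an adjusted p of 3.13e-04. The adjusted p was 0.925 with an estimated correlation. None passed over all genes, and 7 passed adjusted over the list alone, all lower. Usp18, a negative regulator of interferon signalling, stood at 4.24 ± 1.997 FPKM with saline and 1.49 ± 0.557 with exosomes. Ifit2 had a log2 difference of -0.68 and Isg15 of -0.91. Genes of the respiratory chain fell by small amounts, with 29 of 30 tested members lower, a median of -0.21 and an adjusted p of 6.07e-04, where the median of all genes was -0.07. This call was lost with an estimated correlation as well (adjusted p = 0.925). None passed over all genes or adjusted over the list alone. Ndufs1 (31.6 ± 3.24 and 24.1 ± 1.45 FPKM), Cox5b (75.9 ± 5.04 and 61.7 ± 2.74 FPKM) and Ndufb3 (log2 difference -0.35) had the smallest p of the members reported. The highest respiratory chain score, 0.33, was that of saline 2, which also had the highest share of mitochondrially encoded reads and the highest score of adipocyte markers, 1.34. The respiratory chain call held in camera without saline 2 (adjusted p = 0.0417). It was also lost without exosome 2 (adjusted p = 0.103) and with library weights (adjusted p = 0.278).

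**Figure D3:**
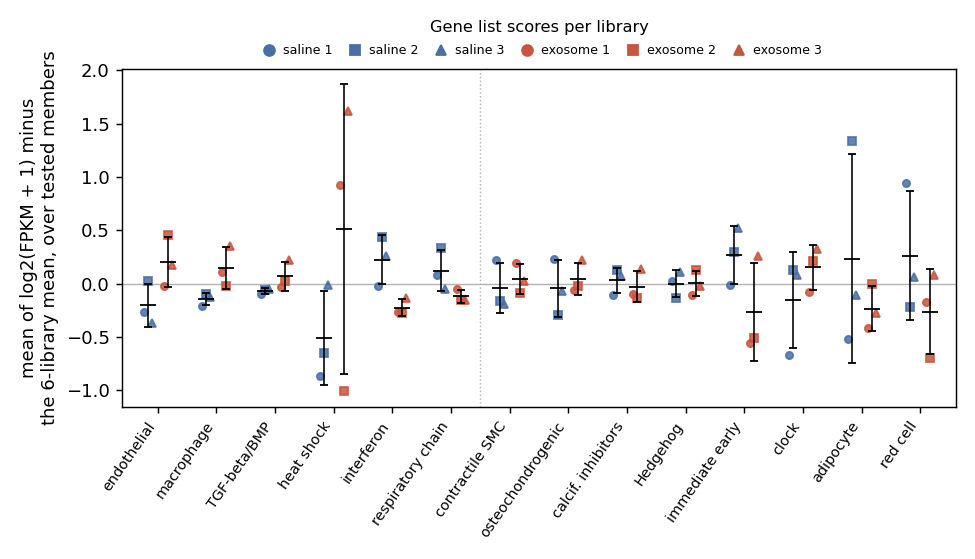
The vertical axis gives the score of each gene list per library, the mean over its tested members of log2(FPKM + 1) minus the 6-library mean. Symbols are single libraries, the bars are the mean ± SD of 3 libraries per group, and the 6 lists left of the dotted line passed camera with its preset correlation. Heat shock scores are high in exosome 1 (0.92) and exosome 3 (1.62) and low in exosome 2 (-1.01).

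The lists closest to the study's subject did not pass. Of 25 contractile smooth muscle genes 14 were higher, with a median of 0.07 and an adjusted p of 0.299. None passed over all genes, and Myocd passed adjusted over the list alone. The list passed with library weights and without saline 1. Nexn (log2 difference 0.45), Des (0.57) and Mrvi1 (-0.38) followed it. Of 14 tested osteochondrogenic genes 9 were higher, with a median of 0.07 and an adjusted p of 0.588, and none passed over all genes or adjusted over the list alone. Ibsp, which encodes bone sialoprotein, stood at 3.05 ± 1.76 and 7.48 ± 3.81 FPKM. Col11a1 (log2 difference -0.53), Chad (0.36) and Postn (0.46) had the next smallest p. Of 11 tested calcification inhibitors 9 were lower, with a median of -0.20 and an adjusted p of 0.622. Smad7 alone passed adjusted over the list alone, as a higher gene, and Fbn1 (log2 difference -0.39), Vkorc1 (-0.26) and Ggcx (-0.29) were lower with groups apart. Of 14 Hedgehog pathway genes 8 were higher, with an adjusted p of 0.724. Gli2 stood at 3.79 ± 1.29 and 1.96 ± 0.280 FPKM, Dhh had a log2 difference of 0.68, Cdon of -0.29 and Hhip of 0.53, and none passed over all genes or adjusted over the list alone.

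Clock genes had an adjusted p of 0.0537, with 12 of 16 tested members higher and a median of 0.48. Adjusted over the list alone, 1 passed as higher and 2 as lower, against none over all genes. Per2 stood at 6.60 ± 1.49 and 19.6 ± 7.33 FPKM, Npas2 at 24.3 ± 5.16 and 13.6 ± 2.40 FPKM, and Nfil3 at 31.7 ± 10.2 and 14.9 ± 2.20 FPKM, and Per1 had a log2 difference of 0.64. Among other settings, the list passed with a pseudocount of 0.1 or 0.01, in the fit on recovered reads, and without saline 2, saline 3, exosome 1 or exosome 2. It did not pass without saline 1 or without exosome 3. Saline 1 carried much of the difference, with a clock score of -0.674 against 0.13 and 0.084 in saline 2 and 3. The scores of exosome 1, 2 and 3 were -0.081, 0.216 and 0.326. Immediate early genes, which respond within minutes to stimulation and to handling of tissue, had an adjusted p of 0.463. Of 22 tested members 14 were lower, and adjusted over the list alone 4 passed as lower and 2 as higher, against none over all genes. Cyr61 stood at 693.7 ± 338.5 and 166.8 ± 13.9 FPKM, Egr3 had a log2 difference of -1.62, Btg2 of -1.32 and Myc of 0.87. Without saline 1, Cyr61 (adjusted p = 0.00188) and Btg2 (adjusted p = 0.0358) passed over all genes, as did the members Atf3, Jun and Klf6. The list passed without saline 1, without exosome 3, and with exosome 1 and 3 both left out.

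None of the other 21 tested lists passed. Genes of the unfolded protein response had an adjusted p of 0.0537 (median 0.09), and they passed without saline 1, saline 2 or exosome 2 and with no filter on low values. Among other settings, red cell genes passed without saline 2, without exosome 3 and with exosome 1 and 3 both left out. Adipocyte markers passed without saline 1, skeletal and cardiac muscle markers with no filter, cytosolic ribosome genes with library weights, and fibrillar collagens with exosome 1 and 3 both left out. Markers of skeletal and cardiac muscle (0.299), red cells (0.299), cytosolic ribosome (0.299), adipocytes (0.468), inflammatory cytokines (0.468), class II antigen presentation (0.574), adventitial fibroblasts (0.588), senescence and DNA damage (0.601), modulated smooth muscle (0.622) and fatty acid oxidation (0.642) had the adjusted p given after each. The adjusted p was 0.724 for fibrillar collagens and matrix, matrix proteases, glycolysis and hypoxia, and antioxidant genes. It was 0.759 for nerve and Schwann cells, 0.793 for autophagy and lysosome, 0.807 for cell cycle and for mesothelium with lymph node, and 0.891 for the Wnt pathway and for calcium and ion channels. Adjusted over the list alone, inflammatory cytokines had 1 member higher (Nfkbia) and 1 lower (Ptgs2), antioxidant genes had 1 higher and 1 lower, and the other 19 lists had none. Neither lymphocyte markers (4 tested) nor markers of neutrophils and mast cells (3 tested) had enough members for the test. Median, mean and test differed in sign for the unfolded protein response (median 0.09, mean -0.04, test higher), inflammatory cytokines (0.22, -0.18, higher) and several lists with medians near 0.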

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

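The fit on recovered reads and the fit with exosome 1 and 3 both left out were chosen after the data were seen. The number of genes higher with exosomes was 1, and it was also 1 under both pseudocounts, both expression filters, TPM, median of ratios, both other moderations, the adjusted threshold of 0.10 and voom on recovered reads. It was 2 with quantile normalization, which added Cd163, 983 with library weights, 0 with exosome 1 and 3 both left out, and 55 at an unadjusted p under 0.05 with at least a 2-fold change. Leaving out each library in turn gave 0 to 2. Genes lower with exosomes were 0, but 2285 with library weights and 63 at the unadjusted 2-fold threshold, and 0 to 7 with each library left out. Without saline 1 the total was 9, without exosome 2 it was 4, without exosome 3 it was 2, and without saline 3 or exosome 1 it was 0. The library weights did not converge and gave exosome 1 a weight of 9.2 against 0.30 to 1.14 for the others, so their counts rest mainly on that library. Gene lists past the threshold were 6, and 7 to 10 with each library left out, the 10 without saline 1. They were 0 with an estimated correlation and 0 with fry. Against the preset 0.01, the estimated correlation was 0.812 for heat shock, 0.557 for endothelial and 0.339 for macrophage markers. It was 0.304 for interferon response, 0.297 for the respiratory chain and 0.046 for TGF-beta and BMP signalling. The preset thus understated the correlation within these lists. With an estimated correlation the unadjusted camera p ran from 0.0633 for TGF-beta and BMP signalling to 0.248 for heat shock. Adjustment gave all 6 lists the same 0.925. For TGF-beta and BMP signalling the unadjusted camera p was 0.000877 with the preset, although its estimated correlation was low. What else added to the loss, and the cause of the fry result, were not tested. Robust moderation has no counterpart in camera and was not run for lists.

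Replicate numbers showed no sign of pairing the libraries. The deviations of same-numbered libraries correlated at 0.068, 0.096 and -0.165, and not every library correlated best with its own number. Such correlations cannot exclude a pairing. With the replicate block 1 gene was called, Zbtb16 (adjusted p = 0.0426), and 8 lists, including all 6 called without it and, in addition, clock genes and red cell genes. Over its alternatives the adjusted p of Zbtb16 ranged from 0.000532 to 0.124.

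Among named genes that did not pass, some signs turned. With exosome 1 and 3 both left out, the log2 difference was -0.032 for Gli1, -0.062 for Acta2, -0.15 for Tagln, -0.23 for Cnn1, 0.24 for Spp1, 0.023 for Mgp, 0.11 for Ezh2, -0.039 for Chordc1, -0.021 for Hsp90ab1, -0.12 for Hsp90aa1 and -0.21 for Hsph1, and the list heat_shock turned to lower (adjusted p = 0.0171), since exosome 2 was the only treated library left. Mgp was at 0.0017 under TPM and 0.041 under median of ratios. Ezh2 was at 2.6e-05 under TPM, 0.031 under median of ratios and 0.084 under quantile normalization. With library weights Myh11 was at 0.083 and Chad at -0.28. With each library left out in turn, the log2 difference ranged from -0.19 to 0.017 for Myh11, from -0.043 to 0.21 for Tagln, from -0.16 to 0.84 for Alpl, from -0.49 to 0.18 for Spp1, from -0.074 to 0.0018 for Mgp and from -0.098 to 0.025 for Ezh2. The median of all genes rose from -0.073 to -0.043 under TPM and -0.006 under median of ratios, and Mgp and Ezh2 moved up by about as much. For the other turns, apart from the heat shock genes, the cause was not tested. Depth of at least 28063355 reads does not limit the abundant genes, while Mir1956, Mir374b and Bglap rest on 21 reads or fewer per library.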

Other observations

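All tests in this part were chosen after the results they bear on were seen. The bound used to set an explanation aside was first 2 standard errors and was widened to a 95% interval with 4 degrees of freedom after the values were known. That change altered 1 reading, named where it applies. For a heat shock response in every treated rat, the score of exosome 2 and then the difference between the groups were tried, and both were dropped because they restate the pattern.

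Genes that glucocorticoids are known to induce stood higher in the exosome libraries. The genes named here were taken from the list tested in the next paragraph, after its values were seen. Fkbp5, the co-chaperone of the glucocorticoid receptor, stood at 6.36 ± 2.74 FPKM with saline and 23.3 ± 6.67 FPKM with exosomes. Tsc22d3, which encodes GILZ, stood at 19.2 ± 4.89 and 47.1 ± 13.2 FPKM, Errfi1 at 121.1 ± 18.1 and 255.3 ± 68.7 FPKM, and Cebpd at 15.2 ± 3.96 and 32.6 ± 7.12 FPKM. None of these passed over all genes (adjusted p from 0.219 to 0.237), and the groups did not overlap for any of the 4. These 4 had the smallest p of the 21 tested members, a choice that favours groups apart. Of all 21 tested members 10 had groups apart, where 21.1% of all genes did. Dusp1 (log2 difference -0.36), Lpin1 (-0.59) and Crispld2 (-0.13), which belong to the same class, were lower.

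Zbtb16, the gene past the threshold, is itself a known glucocorticoid target, and a candidate explanation is glucocorticoid-responsive transcription. A list of such genes, written after the ranking was seen and leaving out those seen in it, had 18 of 21 tested members higher (Per1, Dusp1 and Pdk4 also stood in lists chosen beforehand), a median of 0.63, a camera p of 4.85e-10, a p of 0.0426 with an estimated correlation and a fry p of 0.0308, all unadjusted, unlike the values of the lists chosen beforehand, of which macrophage markers and the respiratory chain had unadjusted fry p of 0.0352 and 0.0443. The score of the glucocorticoid list was 0.70 in exosome 2 against 0.085 and 0.15 in exosome 1 and 3 and -0.52, -0.28 and -0.14 with saline, a difference of 0.62 whose 95% interval, -0.001 to 1.245, reached 0. Scaling between libraries is argued against by the size of the median-of-ratios factors, 0.94 to 1.068. Factors so close together could move the list median only a little. It was 0.709 (standard error of the score 0.17) after that rescaling, which is thus no separate test. The phase of the clock at sampling stays open, with a difference of 0.535 ± 0.551 (SE) in the Per and Dbp arm and of -0.50 ± 0.14 in the Arntl arm. Handling, hormone levels and the exosomes themselves were not tested. The exosomes are confounded with the groups by design, and whether handling or hormone levels differed between the groups is not known.

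Heat shock genes were high in exosome 1 and exosome 3, with Hspb1 at 2803 and 5444 FPKM there, 364 FPKM in exosome 2 and 477 to 1167 FPKM in the saline libraries. The list score of exosome 2, -1.01, lay below all 3 saline scores, and no test remains of whether the treatment moved these genes in every rat. A general stress response with immediate early genes would put the immediate early scores of both libraries above every other library. Neither met this, at -0.55 in exosome 1, the lowest score of all, and 0.261 in exosome 3. The scores were -0.017, 0.293 and 0.525 in saline 1, 2 and 3 and -0.508 in exosome 2. To set the explanation aside, both had to lie below the mean of the other 4 libraries by more than their SD of 0.447. Exosome 3 did not, so the test could not decide.

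The mean scores of endothelial and macrophage markers were higher in the exosome group, by 0.41 (95% interval -0.09 to 0.90) and 0.29 (-0.035 to 0.62), and the endothelial scores overlapped, at -0.019, 0.45 and 0.18 in exosome 1, 2 and 3 and -0.26, 0.02 and -0.37 in saline 1, 2 and 3. A lower share of smooth muscle cells may raise the markers of every other cell type alike, but the contractile score differed by 0.09 (-0.35 to 0.53) and the fibroblast score by -0.007 (-0.32 to 0.30). The excess of the endothelial over the fibroblast score was 0.413 ± 0.190 (SE), with a 95% interval of -0.115 to 0.941, so a lower share stays open under that interval, while under the first bound of 2 standard errors this value counted against it. More perivascular fat with its vessels also stays open, with an excess over the adipocyte score of 0.874 ± 0.465 (SE), an interval of -0.417 to 2.165. The median log2 difference of adipocyte markers was -0.40. The adipocyte difference rested largely on saline 2, with a score of 1.34 against -0.52 and -0.11 in saline 1 and 3. In exosome 1, 2 and 3 the adipocyte score was -0.42, -0.003 and -0.28. A change in the number or state of endothelial cells and macrophages with the treatment stays open as well, and was not tested.

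The 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 1 gene and the highest other split 2, and 3 splits gave at least 1. The real split gave 6 lists and the highest other 16, and all 10 splits gave at least 6. The number of lists called thus did not set the treatment apart from other groupings of the libraries. The median of the glucocorticoid list, taken without its sign, was 0.63 in the real split and 0.43 in the highest other. The split of saline 1, exosome 1 and exosome 3 against the others had 2570 genes at an unadjusted p under 0.05, against 1877 for the real split, which points to a structure of the samples beside the treatment.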
